A study of Felis catus with 16 samples.

How the data were processed

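RNA from 16 samples of dissected cat optic nerve head was made into libraries with a stranded mRNA kit, per the labels' protocols, and sequenced on an Illumina HiSeq, per the series description. The deposited table holds 1 column of FPKM (fragments per kilobase of transcript and per 1e6 mapped fragments) for each sample. Per the submitters' processing notes, FastQC, STAR 2.4.2a and RSEM 1.2.22 were used; whether the counting used strand is not given in the sources used here. The totals of the deposited FPKM values differ between libraries, so no common total was set, and no filter of the authors is recorded in the sources used here. The deposited gene models are those of the Felis_catus_8.0 assembly, and all positions are 1-based coordinates of that assembly. All 25509 genes of the expression table were found in those gene models. The first letter of 722 symbols that begin with G is in lower case there and was restored, 512 genes were named through a RefSeq table of the assembly F.catus_Fca126_mat1.0 by gene number, and 8201 genes keep a LOC number. Chromosome names come from the genes with the same symbol in that RefSeq table, at least 99.7% of which gave the same name for each sequence; no coordinate was taken from it.

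The table holds no counts. Low FPKM values of genes between 400 and 1500 bases fall near whole multiples of the value of 1 fragment, so the depth of each library was estimated from that spacing. Between 95.6% and 96.9% of the values used lay within 0.2 steps of a whole multiple. The estimate returned the depth of a simulated library, and it came to 9.6 to 49.4 in units of 1e6 fragments. These depths serve to compare libraries, and no count test was run. The printed decimals and the gene lengths limit the estimate, which was not checked against read totals.

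Each library was scaled by the median ratio of its FPKM to the geometric mean over genes above 0 in every library. Genes with a scaled FPKM of at least 1 in at least 6 libraries were tested, 14535 in all. The values were taken as log2(scaled FPKM + 0.5), so that fold changes of low genes are understated. FCG was compared with Normal in limma 3.58.1 (R 4.3.3; lmFit and eBayes with trend and robust), with no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. On simulated data made from the 14535 genes, with the real residuals shuffled between libraries in 10 draws and 200 genes changed, limma recovered 76.8% of the genes changed 2-fold and 97.2% of those changed 4-fold on average. The adjusted threshold depends on how many genes change, so these shares need not hold for the real comparison. HP, with a fitted fold of 4.18, was not called there. Unchanged genes called numbered 0 in the median draw and 1040 in the highest. A list of 27 genes shifted 2-fold was called in 10 of 10 draws by camera and by fry, and a list not shifted was called in 0 of 10 by camera and 1 of 10 by fry.

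Before the data were examined, 51 gene lists were fixed, for glial, immune, matrix, stress and cell-type genes. A list was tested when at least 3 members were among the genes tested, which held for 49 lists; the erythrocyte list had 1 such member and the sex-linked list 0. Lists were tested with camera with an estimated correlation between genes, and fry was run beside it; fry asks whether a list's genes move one way on balance and does not compare them with other genes. For each list, members were also counted with p-values adjusted over the list alone. The lists described were picked from the 49 after their results were seen. The genes to be named were fixed as LTBP2, the 12 largest rises and 12 largest falls past the threshold, and, of each list described, up to 4 members past the threshold or else the 2 with the highest mean scaled FPKM. No gene passed the threshold, so further genes are named by rules chosen after their values were seen: up to 4 members with the smallest p among those that passed over the list alone, up to 12 genes per direction with an adjusted p under 0.1, a symbol and a mean of at least 5 scaled FPKM in the higher group, and the 7 list members UBE2C, TOP2A, MKI67, CCNA2, MCM5, MYD88 and COL1A1. Some genes that these rules name are not reported here and were not replaced; they stay in the tests and in the list counts.

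Distances between libraries and LTBP2 were also tested with two-sided exact permutation tests over the 8008 splits of 16 libraries into 10 and 6. Correlations between the scores of 4 lists used 100000 permutations within FCG and all permutations within Normal. The alternatives were other pseudocounts, filters and scalings, eBayes without robust, limma array weights, an exact rank-sum test, list means as covariates for tissue makeup, the shared replicate numbers as a block, other list tests, and leaving out each library. The count of members adjusted over a list alone was recomputed under each of these settings, which was decided after seeing that no gene passed. Covariates for depth and for 3 tissues together, and fits without the 2 low-weight and without the 2 shallowest libraries, were added after seeing the data. Sex, age, eye and litter are not labelled and were not modelled.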

Results

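Gene expression was measured in the optic nerve head, the region where the axons of retinal ganglion cells leave the eye, of 10 cats with feline congenital glaucoma (FCG) and 6 normal cats of similar age (Normal). The FCG cats are homozygous for a mutation of LTBP2, which encodes a matrix protein that binds latent TGF-beta complexes and microfibrils. The comparison asks which transcripts of glia, immune cells, matrix and neurons differ in the glaucomatous tissue. Estimated depth, in units of 1e6 fragments, was 10.3 to 43.3 in FCG (median 30.8) and 9.6 to 49.4 in Normal (median 16.7). Between 18003 and 19780 genes had an FPKM above 0 in a library. No pair of libraries was a duplicate: their correlations over the tested genes ran from 0.828 to 0.981. Each label is taken as 1 cat, and p-values measure the spread between these libraries.

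LTBP2 transcript (identifier gene9482, chromosome B3 from 119826489 to 119934001 on the minus strand, 37 exons in the annotation) had similar means in both groups. It measured 7.27 ± 2.89 scaled FPKM in FCG (SD, n = 10; range 4.17 to 11.9) and 7.32 ± 1.14 in Normal (SD, n = 6; range 6.13 to 9.06). The log2 fold change was -0.08 ± 0.21 (SE; adjusted p = 0.866 in limma), and a two-sided exact permutation test gave p = 0.716. The FCG libraries were split, however. Replicates 1 to 6 measured 4.17 to 6.11, all below the lowest Normal library. Replicates 7, 9 and 10, which had the highest COL1A1 of the group, measured 11.9, 11.4 and 10.4, all above the highest Normal library. Whether this split follows tissue makeup was not tested. A mutation within the coding part need not lower the transcript, so the LTBP2 level does not check the labels.

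The pieces of tissue differed widely in the cell types they held. The mean log2(scaled FPKM + 0.5) of the photoreceptor and retina list ranged from 6.69 to 9.31 in FCG and from 5.09 to 9.69 in Normal. MGP, a matrix protein abundant in sclera and vessels, ranged from 1472 to 23672 scaled FPKM in FCG and from 789 to 2922 in Normal, and DCT, a pigment cell enzyme, ranged 83.6-fold within FCG and 268-fold within Normal. The first principal component of the 16 libraries carried 39.3% of the variance and the second 22.2%. The first correlated with the photoreceptor list mean (r = 0.85) and the fibroblast list mean (r = -0.73). The second correlated most with the myelin list mean (r = -0.71). The median log2 fold change was -0.32 for the photoreceptor and retina list, -0.37 for the mature oligodendrocyte and myelin list and 0.84 for the fibroblast, sclera and meninges list. In each of these lists 0 members passed over all genes and 0 when adjusted over the list alone. However, 5 fibroblast members passed over the list alone without FCG replicate 1 and 3 without Normal replicate 6. With the photoreceptor covariate 5 myelin members were lower over the list alone, at a median of -0.53 (fry adjusted p = 0.0914). With array weights the myelin median was -0.66. The camera adjusted p of the photoreceptor, myelin and fibroblast lists was 0.765, 0.720 and 0.426 with an estimated correlation.

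**Figure D1:**
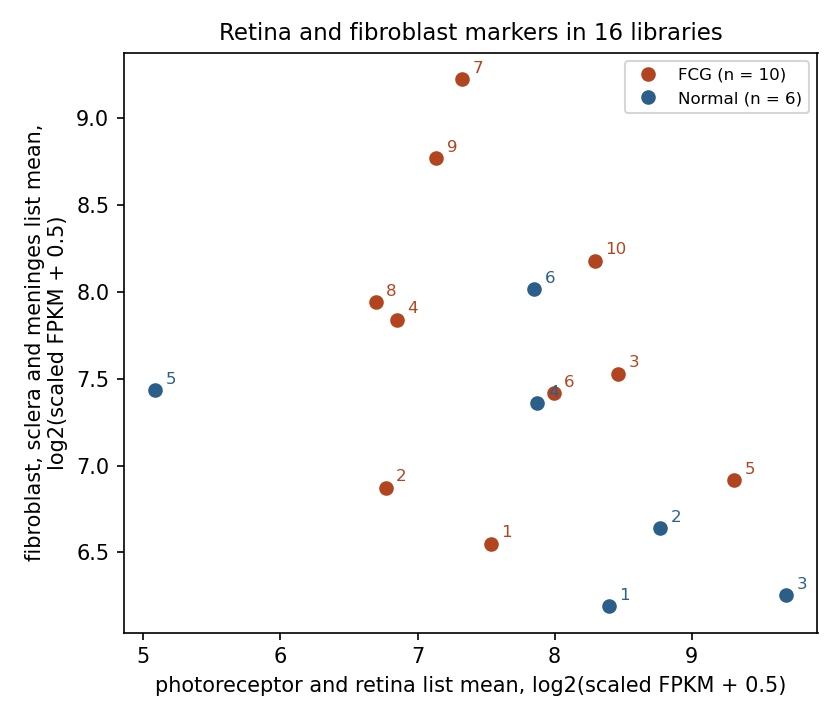
Mean log2(scaled FPKM + 0.5) of the photoreceptor and retina list (horizontal axis) and of the fibroblast, sclera and meninges list (vertical axis) in each library, with replicate numbers beside the points, for FCG (n = 10) and Normal (n = 6). Both groups spread widely along both axes and overlap, and FCG replicate 7 has the highest fibroblast value.

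No gene passed the threshold, and those with the smallest adjusted p include HP, UPK1B, LGALS3, A2M and SLC14A1. HP, the haemoglobin-binding protein haptoglobin (gene21866, chromosome E2 from 47091962 to 47094976), measured 285 ± 234 scaled FPKM in FCG (SD, n = 10) and 57.0 ± 16.3 in Normal (SD, n = 6), a log2 fold change of 2.07 ± 0.36 (SE). The uroplakin gene UPK1B had a log2 fold change of 2.13 ± 0.45, the galectin gene LGALS3 1.41 ± 0.30, the protease inhibitor gene A2M 1.32 ± 0.25, and FABP5, which encodes a fatty-acid-binding protein, 1.03 ± 0.20. The urea transporter gene SLC14A1, which is expressed in astrocytes among other cells, measured 7.16 ± 4.18 in FCG and 22.7 ± 10.8 in Normal, a log2 fold change of -1.69 ± 0.35. TMEM176B and TMEM176A stood at -1.53 ± 0.32 and -1.40 ± 0.30; they overlap on chromosome A2, so their fragments may not be fully separable. All 10 FCG libraries lay above the median Normal library for HP, UPK1B, LGALS3, A2M and FABP5, and 0 of 10 for SLC14A1, TMEM176B and TMEM176A. These genes were picked for a small p in the same libraries, so such separation adds no support beyond it.

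In the test over all genes limma called 0 genes higher and 0 lower of 14535, and so 0 changed at least 2-fold; the exact rank-sum test also called 0. At an unadjusted p under 0.05 limma had 2084 genes, 1351 higher and 733 lower in FCG, where 727 would be reached with no difference, and the rank-sum test had 2028. The smallest adjusted p was 0.0862, and 34 genes had an adjusted p under 0.1 (23 higher and 11 lower), among them HP, BCO2 and PTGR1 (0.0862 each) and UPK1B, LGALS3, A2M, UCP2, LXN, FABP5, SERPINB9, GGH, TYMS, MCM6, SLC14A1, TMEM176B, TMEM176A, SMIM17, DCUN1D2, TRUB1 and PRKCZ (0.0868 each). With limma array weights 740 genes were higher and 329 lower, including all 34, and with the myelin list mean as a covariate 60 were higher and 16 lower, 68 of those 76 being called with weights too in the same direction. Without the 2 libraries of lowest weight, FCG replicate 7 and Normal replicate 3, 0 genes were called in limma without weights. Leaving out FCG replicate 1 gave 26 higher and 17 lower, FCG replicate 5 gave 11 and 1, FCG replicate 7 gave 2 and 0, Normal replicate 1 gave 3 and 4, and Normal replicate 6 gave 1 and 1.

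**Figure D2:**
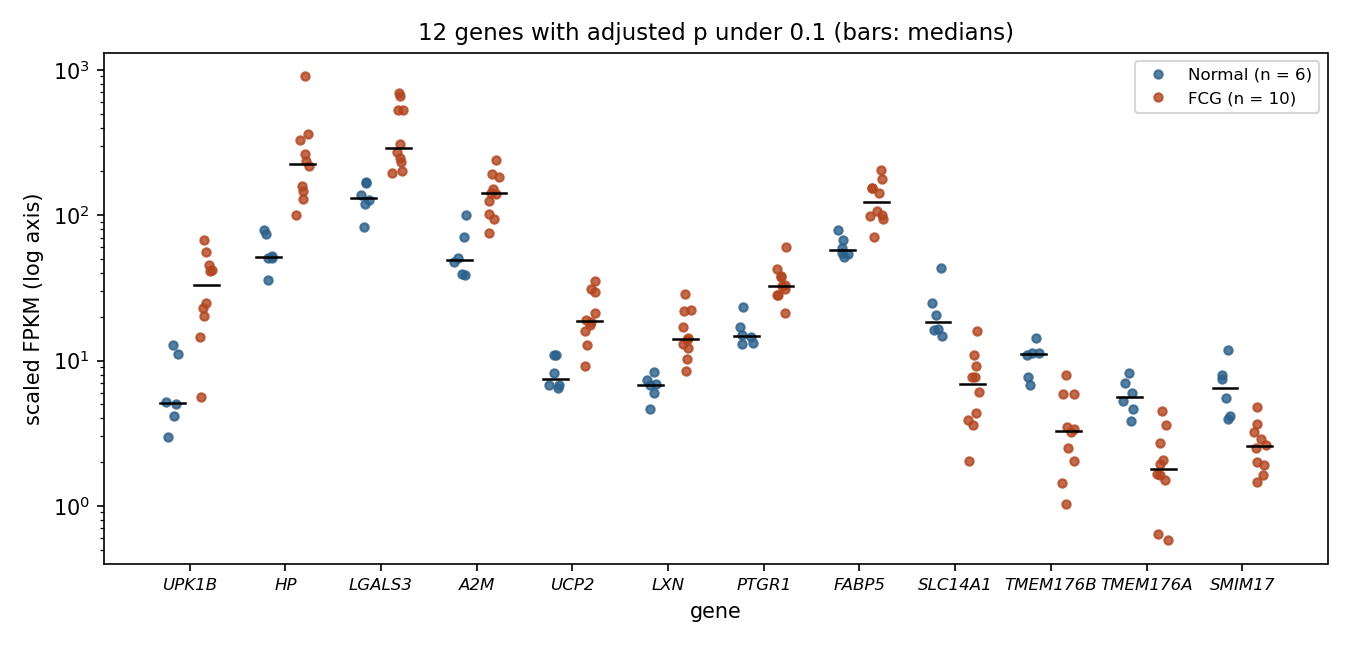
Scaled FPKM on a log axis of 12 genes with an adjusted p under 0.1 in limma, 1 point per library, FCG (n = 10) and Normal (n = 6), with medians as bars. Each of the 8 genes on the left has a higher median in FCG and each of the 4 on the right a lower one, and none has an adjusted p under 0.05.

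Cell cycle genes had the largest share of members past the threshold within their own list among the 49 lists. Of 27 tested members, 25 had a positive log2 fold change and the median was 0.58. RRM2, the ribonucleotide reductase subunit made in S phase, measured 5.20 ± 1.88 scaled FPKM in FCG (SD, n = 10) and 2.16 ± 0.62 in Normal (SD, n = 6), a log2 fold change of 1.05 ± 0.23 (SE). TYMS, which makes thymidylate, stood at 0.71 ± 0.14, the helicase gene MCM6 at 0.55 ± 0.11 and the mitotic kinase gene CDK1 at 0.74 ± 0.17. For each of them all 10 FCG libraries lay above the median Normal library. These members were picked for a small p in the same libraries, so that separation adds no support. UBE2C (1.32 ± 0.30), TOP2A (1.0 ± 0.27) and the proliferation marker gene MKI67 (0.67 ± 0.22) also passed over the list alone, while CCNA2 (-0.29 ± 0.35) and MCM5 (-0.12 ± 0.19) had negative values. MKI67 was low, at 1.31 ± 0.51 scaled FPKM in FCG and 0.62 ± 0.26 in Normal, near the filter of 1. PCNA, with 43.3 ± 3.33 against 38.3 ± 4.68 scaled FPKM the most abundant member, stood at 0.18 ± 0.08.

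Over all genes 0 of the 27 members passed, and 19 were higher and 0 lower when adjusted over the list alone. The list was called higher by fry (adjusted p = 0.0153), the 1 list that was, and not by camera (adjusted p = 0.426 with an estimated correlation). The fry call was lost without Normal replicate 1, 3 or 4 (adjusted p = 0.0527, 0.0531 and 0.0552). The same held without the 2 low-weight libraries FCG replicate 7 and Normal replicate 3 (0.0679) and with FPKM rescaled to TPM (0.125). It was also lost with the fibroblast list mean as a covariate, and with the replicate numbers as a block over 12 libraries (0.201). Without the block the same 12 libraries gave a fry adjusted p of 0.0483. With the photoreceptor, myelin and fibroblast list means together as covariates, an alternative added after seeing the data, 11 members were higher when adjusted over the list alone, and the fry adjusted p was 0.294.

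**Figure D3:**
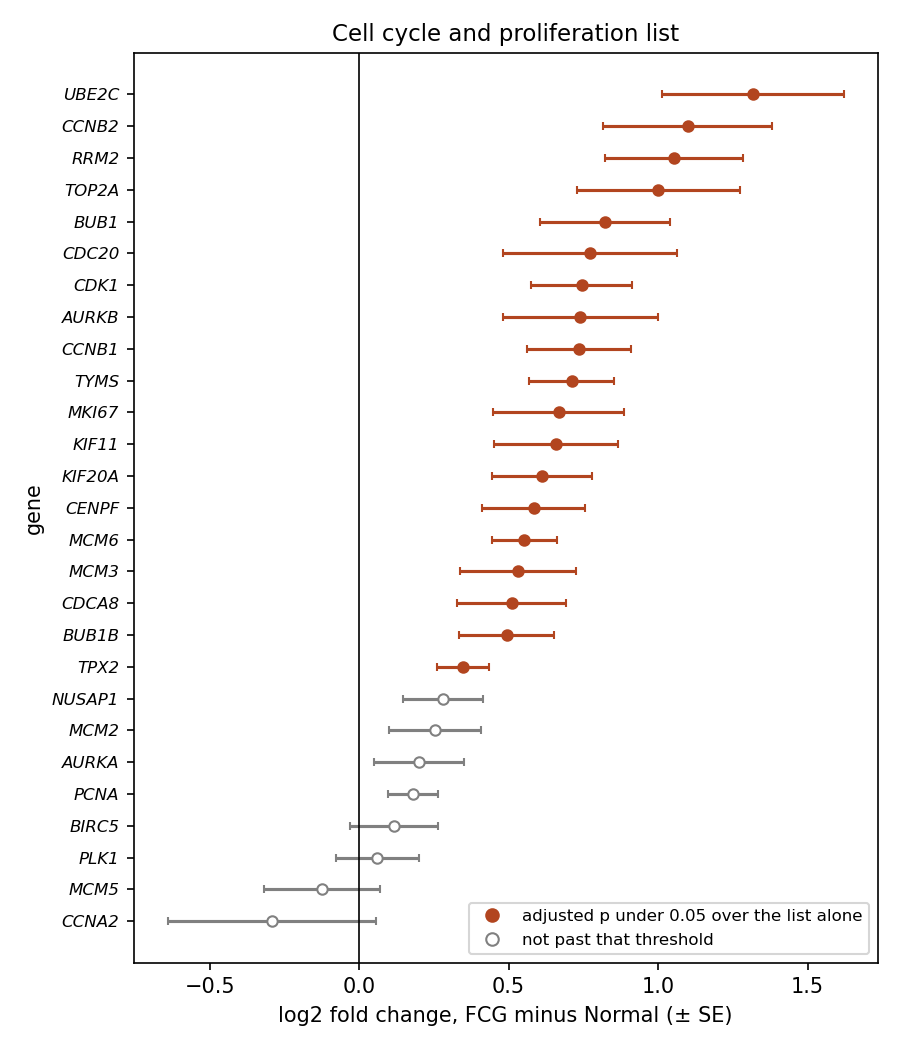
Log2 fold change (FCG minus Normal) with its SE of the 27 tested members of the cell cycle and proliferation list, from limma over 10 FCG and 6 Normal libraries. The 19 filled points have an adjusted p under 0.05 over the list alone, all of them above 0, and none passes over all genes.

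Complement genes had a median log2 fold change of 0.75, positive in 13 of 13 members, without a call for the list. The membrane regulator gene CD59 measured 188 ± 59.6 scaled FPKM in FCG (SD, n = 10) and 107 ± 13.1 in Normal (SD, n = 6), a log2 fold change of 0.76 ± 0.18 (SE). C1S, a protease of the classical pathway, stood at 1.03 ± 0.33, its inhibitor gene SERPING1 at 0.68 ± 0.22 and C1QC, expressed by microglia, at 0.92 ± 0.32; CFI stood at 0.58 ± 0.27. Over all genes 0 members passed, and 7 were higher when adjusted over the list alone; the list itself was not called (adjusted p = 0.426 with an estimated correlation, fry adjusted p = 0.0861). With the fibroblast list mean as a covariate the 7 became 0, as they did with all 3 tissue covariates. Leaving out FCG replicate 3, 5, 8 or 9 gave 4, 12, 1 and 3, and leaving out Normal replicate 1, 2, 3 or 5 gave 1, 1, 1 and 11.

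Cytokine and Toll-like receptor genes had positive values in 14 of 14 and 19 of 20 members, without a call for either list. Their median log2 fold changes were 0.45 and 0.28. IL10, an anti-inflammatory cytokine gene, had 3.25 ± 1.33 scaled FPKM in FCG (SD, n = 10) and 1.40 ± 0.64 in Normal (SD, n = 6), a log2 fold change of 0.98 ± 0.24 (SE); LIF (1.07 ± 0.32), IL1A (0.98 ± 0.35) and IL18 (0.66 ± 0.19) also passed over the list. LIF was low, at 2.98 ± 2.33 scaled FPKM in FCG and 0.97 ± 0.32 in Normal, where its mean was below the filter of 1. The most abundant members of the cytokine list did not pass over it, with SPP1 at 0.02 ± 0.32, negative with FPKM as deposited, rescaled to TPM or quantile normalized, and CXCL12 at 0.54 ± 0.39. CD14, the lipopolysaccharide co-receptor of monocytes and microglia, measured 9.55 ± 6.13 against 3.27 ± 0.61 (log2 fold change 1.25 ± 0.28), and LY96 (0.67 ± 0.16), IRAK4 (0.52 ± 0.14), TLR2 (0.53 ± 0.16) and MYD88 (0.56 ± 0.18) also passed over the list. RELA and NFKBIA, the most abundant members, stood at 0.32 ± 0.21 and 0.04 ± 0.22, the second changing sign with FPKM as deposited, rescaled to TPM or quantile normalized. Over all genes 0 members of either list passed; adjusted over the list alone, 5 of 14 cytokine and chemokine members and 6 of 20 Toll-like receptor and NF-kB members were higher. Without Normal replicate 3 these became 1 and 3, and with the fibroblast list mean as a covariate 0 and 0. Without FCG replicate 4, 6, 9 or 10 or Normal replicate 1 or 5 the cytokine count was 3, and without Normal replicate 4 it was 2. Neither list was called by camera (adjusted p = 0.426 for both with an estimated correlation) or by fry (0.0959 and 0.137).

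Microglial genes showed positive medians and few members past any threshold. In the microglia and macrophage list, 14 of 15 members were positive with a median of 0.52; 0 passed over all genes and 0 when adjusted over the list alone. Its most abundant members, the protease gene CTSS and the adaptor gene TYROBP, stood at 0.73 ± 0.25 and 0.62 ± 0.33 (SE). Among disease-associated microglial genes, LGALS3 and CLEC7A (0.88 ± 0.27) were the 2 of 15 that were higher when adjusted over the list alone. The 9 homeostatic microglial members had a median of 0.37, with OLFML3 at 0.37 ± 0.33. In the infiltrating macrophage and monocyte list 1 of 8 was higher (CD14), with LYVE1 at 0.52 ± 0.27 and VCAN at 0.27 ± 0.28. With the myelin list mean as a covariate 14 microglia and macrophage, 8 disease-associated and 6 infiltrating members were higher over the list alone, with the photoreceptor covariate 7, 3 and 3, with array weights 4, 2 and 3, and with all 3 tissue covariates 1, 0 and 0. With all 3, the medians of these 3 lists were still positive (0.36, 0.30 and 0.24), as was that of homeostatic microglia (0.32), whose count is not given here. Leaving out single libraries gave 1 to 4 disease-associated members (4 without FCG replicate 5) and 1 to 6 infiltrating members (6 without Normal replicate 6). The microglia and macrophage count of 0 became 12 without FCG replicate 5, 2 without FCG replicate 1, 5 without FCG replicate 10, and 6 and 3 without Normal replicate 5 and 6. Over all genes 0 members of these lists passed, and the camera adjusted p was 0.426 for 3 of the lists and 0.464 for homeostatic microglia with an estimated correlation.

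No difference was detected in astrocyte identity genes, while several reactive astrocyte genes passed within their own list. GFAP, the astrocyte intermediate filament, measured 4688 ± 2179 scaled FPKM in FCG (SD, n = 10) and 4622 ± 1603 in Normal (SD, n = 6), a log2 fold change of -0.03 ± 0.31 (SE). Glutamine synthetase (GLUL) stood at -0.05 ± 0.12 and VIM at 0.30 ± 0.21, the latter negative after quantile normalization. The copper carrier gene CP measured 51.9 ± 10.2 against 31.8 ± 8.64 (0.71 ± 0.16), and the hyaluronan receptor gene CD44 (0.87 ± 0.24), the matrix gene TNC (1.06 ± 0.29) and the oncostatin receptor gene OSMR (0.79 ± 0.25) also passed over the list alone, with TIMP1. Adjusted over the list alone, 5 of 14 reactive astrocyte members were higher, as were 4 of 7 in the neurotoxic (A1) set (SERPING1, SRGN, FBLN5 and GGTA1) and 2 of 10 in the neuroprotective (A2) set (CD14 and TM4SF1). SERPING1, SRGN, FBLN5 and GGTA1 were the only tested A1 members with positive values. SRGN stood at 0.71 ± 0.23, FBLN5 at 0.68 ± 0.28, GGTA1 at 0.53 ± 0.18, TM4SF1 at 0.59 ± 0.20 and S100A10, the most abundant A2 member, at 0.43 ± 0.25. Without Normal replicate 3 the first 2 counts became 3 and 0, and without Normal replicate 1 the A1 count was 2, while the A2 count was 1 to 4 (4 without FCG replicate 5 or Normal replicate 6). With the fibroblast list mean as a covariate the reactive, A1 and A2 counts were 1, 0 and 1, with all 3 tissue covariates 2, 0 and 0, and with TPM the A1 count was 0; the A2 count was 7 with the myelin covariate. The general astrocyte list had 0 of 12 by that count and a median of -0.02. Over all genes 0 members of the 4 lists passed, and the camera adjusted p was 0.426 for the 3 reactive lists and 0.765 for the astrocyte list with an estimated correlation.

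Extracellular matrix genes had positive medians in FCG and varied strongly between libraries. All 18 collagens tested had positive values, with a median log2 fold change of 0.72. Much of this came from FCG replicates 7 to 10, whose collagen list means were 5.89 to 7.22 on the log2 scale. FCG replicates 1 to 6 had 4.54 to 5.45, within the Normal range of 3.93 to 6.13. COL1A2 measured 1927 ± 1992 scaled FPKM in FCG (SD, n = 10) and 697 ± 525 in Normal (SD, n = 6), a log2 fold change of 1.08 ± 0.63 (SE), with COL3A1 at 0.99 ± 0.49 and COL1A1 at 1.18 ± 0.80; 0 collagens passed over all genes and 0 when adjusted over the list alone. Among glycoproteins and proteoglycans, 5 of 22 were higher over the list alone, including the proteoglycan gene NCAN (58.4 ± 25.4 against 25.5 ± 8.07; 1.13 ± 0.26), TNC, LAMB1 (0.83 ± 0.29) and POSTN (0.80 ± 0.23). The abundant members SPARC (0.75 ± 0.37) and DCN (0.77 ± 0.42) were not. All 21 elastic fibre and microfibril members tested, among which LTBP2 was not counted, had positive values. EFEMP1 (0.92 ± 0.21) was the 1 higher over the list alone, and FBLN1 and MFAP5 stood at 1.08 ± 0.43 and 0.75 ± 0.30. Of 18 proteases and inhibitors, MMP19 (1.53 ± 0.35) and PLAU (0.84 ± 0.20) were higher over the list alone, and TIMP1 (0.81 ± 0.29) and TIMP3 (0.54 ± 0.22) did not pass over this list.

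Over all genes 0 members of the 4 matrix lists passed. The camera adjusted p was 0.482 for the collagens and 0.426 for the other 3 with an estimated correlation, and fry gave 0.272 for the collagens, 0.137 for glycoproteins, 0.196 for elastic fibres and 0.137 for proteases. With the fibroblast list mean as a covariate, COL1A2 (-0.10), COL1A1 (-0.31) and DCN (-0.02), members of that list too, and VCAN (-0.14) turned negative, and the 5 glycoprotein and 1 elastic fibre members over the list alone became 1 and 0. Without FCG replicate 5 the counts over the list alone were 9 for glycoproteins, 9 for elastic fibres and 7 for proteases, without FCG replicate 1 they were 8, 6 and 5, and without Normal replicate 3 glycoproteins had 1. Without Normal replicate 6 the collagens had 3, elastic fibres 5 and proteases 6. With the photoreceptor, myelin and fibroblast list means together as covariates glycoproteins had 1, elastic fibres 0 and proteases 0.

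**Figure D4:**
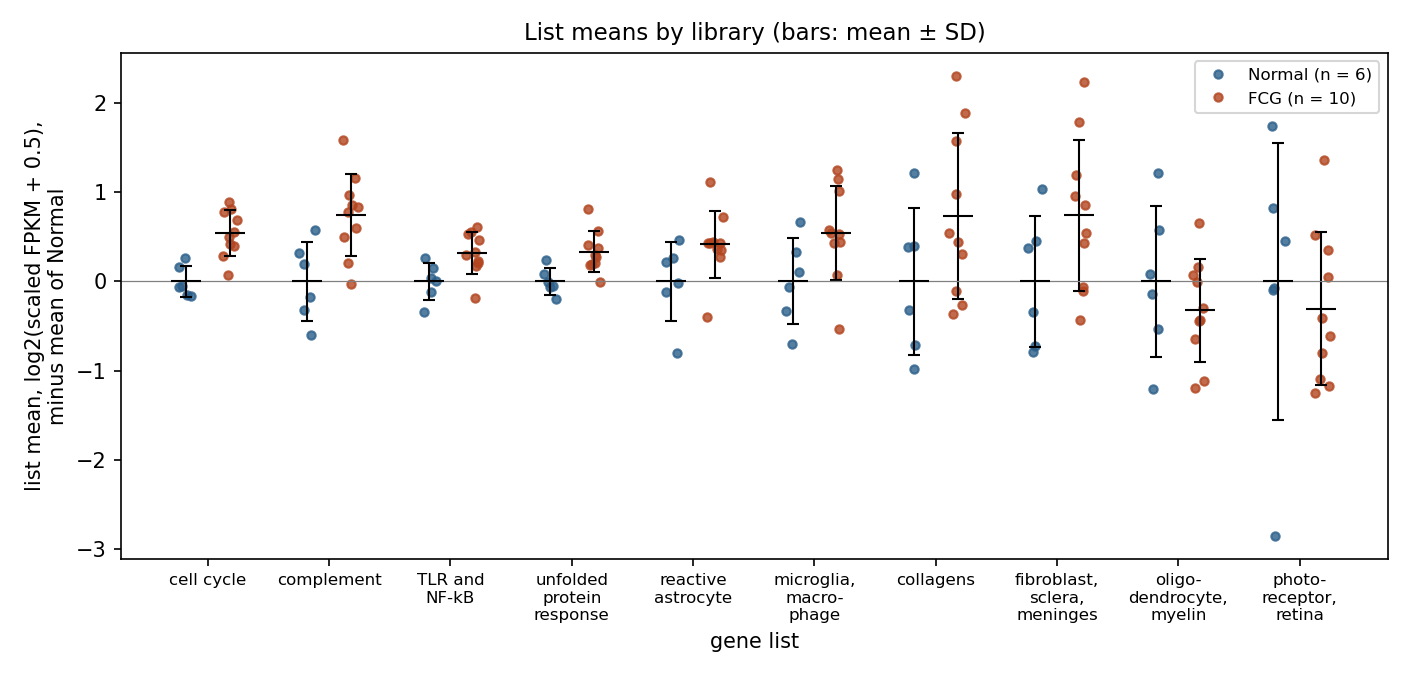
Mean log2(scaled FPKM + 0.5) of 10 gene lists in each library, minus the mean of the Normal libraries, with the mean and SD of FCG (n = 10) and Normal (n = 6). The collagen, fibroblast, myelin and photoreceptor values spread over a wide range in both groups, and no list was called by camera.

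Protein-folding genes had small positive values. HSP90B1, an endoplasmic reticulum chaperone, measured 344 ± 34.0 scaled FPKM in FCG (SD, n = 10) and 263 ± 36.5 in Normal (SD, n = 6), a log2 fold change of 0.39 ± 0.10 (SE). The stress transcription factor gene ATF3 (0.79 ± 0.21), MANF (0.49 ± 0.14) and EDEM1 (0.42 ± 0.13) also passed over the list alone, with CALR at 0.27 ± 0.12 and ATF4 at 0.24 ± 0.15. Of the 17 unfolded protein response members, 0 passed over all genes and 6 were higher when adjusted over the list alone (adjusted p = 0.426 with an estimated correlation, fry adjusted p = 0.0861). Ribosomal protein genes had a median of 0.43, with RPL5 (0.67 ± 0.19), RPL4 (0.51 ± 0.16) and RPL7 (0.63 ± 0.19) higher over the list alone, 3 of 21. Again 0 passed over all genes (adjusted p = 0.426 with an estimated correlation), fragments of these genes can be shared with processed pseudogenes, and FCG replicate 7 stood far above the other FCG libraries. With quantile normalization the 3 ribosomal members became 0, with array weights 17 and without FCG replicate 7 they became 15; over all libraries left out in turn the count ran from 0 to 15. With the fibroblast covariate or all 3 tissue covariates both counts became 0, the unfolded protein response median being 0.12 with all 3. The unfolded protein response count was 10 without FCG replicate 1, and 2 and 3 without Normal replicate 1 and 3.

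Cholesterol synthesis genes had negative values in 20 of 20 members and a median log2 fold change of -0.43. HMGCS1, an enzyme of the mevalonate pathway, measured 129 ± 59.1 scaled FPKM in FCG (SD, n = 10) and 258 ± 152 in Normal (SD, n = 6), a log2 fold change of -0.89 ± 0.34 (SE). CYP51A1, a sterol demethylase, stood at -0.53 ± 0.26. The median was -0.094 with the photoreceptor, myelin and fibroblast list means together as covariates and -0.22 with the myelin list mean alone. None of the 20 passed over all genes or when adjusted over the list alone, 0 in both counts. The list was not called (camera adjusted p = 0.426 with an estimated correlation, fry adjusted p = 0.196). With array weights 6 members were lower over all genes and 15 over the list alone, and fry called the list lower (adjusted p = 0.0421). With the photoreceptor covariate 12 were lower over the list alone, at a median of -0.50 and a fry adjusted p of 0.0696. Neuronal and myelin genes also had negative medians and wide spread. UCHL1 and SNAP25, the most abundant of the retinal ganglion cell and neuron list (median -0.51), stood at -0.10 ± 0.15 and -0.65 ± 0.62. MBP of myelin stood at -0.41 ± 0.39, SAG of photoreceptors at -0.19 ± 0.56 and PTGDS of meninges at -0.04 ± 0.42. The neuron list had 0 members past the threshold over all genes and 0 adjusted over the list alone (adjusted p = 0.764 with an estimated correlation).

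No list was called by camera. With an estimated correlation 0 of 49 lists were higher and 0 lower, 4 having an unadjusted p under 0.05 (cell cycle, complement, neuroprotective astrocyte and unfolded protein response), whereas fry called 1 list and had 15 at an unadjusted p under 0.05. The fry count was 18 with the myelin covariate, 6 with the photoreceptor covariate, 6 higher and 1 lower with array weights, 3 with the stricter filter, and 0 with the fibroblast covariate, all 3 tissue covariates, TPM or without the 2 low-weight libraries. It was 13 without FCG replicate 5, 4 without Normal replicate 6, 2 without FCG replicate 1 or 9, and 0 without Normal replicate 1, 3 or 4. With the preset correlation of 0.01 camera called 25 lists higher and 4 lower; none of these calls held with an estimated correlation.

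The spread among FCG libraries and among Normal libraries was compared as distances. The mean of 1 minus the Pearson correlation was 0.0551 within FCG, 0.0630 within Normal and 0.0657 between groups. A two-sided exact permutation test over 8008 splits gave p = 0.736 for the difference within groups and p = 0.0830 for the excess of the distance between groups over that within. Leaving out FCG replicate 5 or Normal replicate 5 brought the second p to 0.0286 and 0.0236 in the same exact permutation test.

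Within the 10 FCG cats, microglial, reactive astrocyte and cell cycle scores correlated by Pearson r of list means, and not past the threshold by Spearman rho or with list medians. Of 6 pairs among 4 lists, microglia with reactive astrocyte gave Pearson r = 0.80 (permutation p = 0.0126, adjusted 0.0379) and Spearman rho = 0.66 (permutation p = 0.0435, adjusted 0.218). Microglia with cell cycle gave r = 0.78 (permutation p = 0.00699, adjusted 0.0379) and rho = 0.60 (permutation p = 0.0727, adjusted 0.218), and reactive astrocyte with cell cycle r = 0.69 (permutation p = 0.0200, adjusted 0.0400) and rho = 0.33 (permutation p = 0.350, adjusted 0.525). Without the 2 libraries farthest from the median of the first list, r was 0.48, 0.57 and 0.14, so these relations rest in part on those libraries. With the median of each list as the score r was 0.74, 0.76 and 0.67, with adjusted permutation p of 0.0764, 0.0575 and 0.0764. The 3 pairs with collagens had r = 0.31, 0.32 and 0.50 with adjusted permutation p from 0.208 to 0.391. In the 6 Normal cats, microglia with reactive astrocyte gave r = 0.91 (exact permutation p = 0.00694, adjusted 0.0417) and rho = 0.94 (exact permutation p = 0.0167, adjusted 0.05). Collagens with microglia gave r = 0.82 and rho = 0.94, and collagens with reactive astrocyte r = 0.82 and rho = 0.89, with adjusted exact permutation p of 0.0806 for both r and 0.05 and 0.0667 for rho. The 3 pairs with cell cycle gave r = 0.70, 0.54 and 0.68 and rho = 0.60, 0.54 and 0.66, with adjusted exact permutation p from 0.178 to 0.297. Whether correlations differed between FCG and Normal was not tested. The scores were not adjusted for tissue makeup. FCG replicate 5, highest of FCG in the photoreceptor list mean (9.31), was lowest for microglia (3.30), reactive astrocyte (4.88) and cell cycle (1.82). Normal replicate 3, highest of Normal (9.69), was likewise lowest of Normal (3.13, 4.48 and 1.58). A shared effect of the amount of retina therefore cannot be told apart from linked responses.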

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

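The tests of the counts made with library weights or without low-weight libraries, at an unadjusted p, by fry, with the preset correlation, with the myelin covariate or any of 5 covariate fits, over the other described lists and over all 49 lists were chosen only after the result was seen. A library was singled out when its gap to the nearest other library of its group was unusually large for the group's range. Of 278 groups of values tested, 15 met this, where 13.9 would by chance at 1 in 20, but 11 of the 15 lie in 1 library, FCG replicate 7.

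FCG replicate 7 had the highest FPKM total of its group, 689953 against 594428 for the next library, and the lowest scale factor, 0.817 against 0.975. On the log2 scale its ribosomal protein list mean was 10.98 (next 10.03), with RPL4 at 11.14 (10.48), RPL5 at 10.88 (10.22) and RPL7 at 12.23 (11.42). It was also highest for GPX3 at 8.0 (7.24), IER3 at 6.41 (5.22), NFKBIA at 6.42 (5.50) and TIMP3 at 9.50 (8.65), and lowest for EDNRB at 4.37 (6.14). FCG replicate 5 was lowest for MKI67 at -0.27 (next 0.56) and TOP2A at 1.06 (1.88). Among Normal libraries, replicate 5 was highest for NFE2L2 at 6.60 (6.37) and replicate 3 lowest for OSMR at 3.86 (4.82).

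The first pattern weighed is the larger number of genes called when libraries are weighted, 1069 against 0. Leaving out the lowest-weight libraries did not reproduce that number. Without FCG replicate 7 and without weights 2 genes were called, and without FCG replicate 7 and Normal replicate 3 together 0. Noise of these libraries as the source is not decided by this, since fewer libraries remain and the weights also raise others. Weights were 4.11 for FCG replicate 6 and 3.29 for Normal replicate 4, the highest, against 0.159 for FCG replicate 7 and 0.318 for Normal replicate 3. Chance cannot be excluded: 6 of 100 splits of the libraries gave as many genes with weights refitted, the highest other 3601. That split calls several times the real count, which points to a structure of the samples that was not traced.

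The second pattern is the cell cycle list, whose mean was 0.54 ± 0.12 (SE) higher in FCG on the log2 scale. A difference in depth is argued against as the whole source, since the value was 0.52 ± 0.13 with log2 depth as a covariate. For this list taken alone, 1 of 100 splits (the real one) gave as many as 19 members, the highest other giving 14. Some list reached as large a share in 9 of 100 splits. The smallest fry p of any list was as small in 1 of 100 splits, the real one. These measures over all lists differ, so chance is not excluded once the picking of this list among many is counted. A different mix of retina, myelin and sclera in the pieces cannot be told apart from proliferation, since with those 3 covariates the value was 0.40 ± 0.13, an interval that spans the bound set for the test. Dividing glia or immune cells in FCG remain an open, untested hypothesis.

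The third pattern is the positive values of the matrix glycoprotein and proteoglycan list. Less retina in the FCG pieces is argued against, narrowly, by a difference of 0.53 ± 0.22 with the photoreceptor covariate against 0.60 ± 0.26 without. More scleral and meningeal tissue cannot be told apart from more matrix: for members outside the fibroblast list the difference was 0.19 ± 0.13 with that list as a covariate and 0.58 ± 0.25 without. Fibroblasts that make more matrix would move both alike, which keeps it open.

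For the remaining counts, other splits showed the following. The 0 genes of the test over all genes and the 0 lists of camera are matched by 100 of 100 splits each, as any count of 0 must be, so the splits decide nothing there (highest other 264 genes and 1 list). Chance is not excluded for the 2084 genes at an unadjusted p under 0.05 (7 of 100, highest other 4297) or the 29 lists with the preset correlation (20 of 100, highest other 37). Few splits gave as many as the 1 list of fry (3 of 100, highest other 5). The same held for the 76 genes with the myelin covariate (1 of 100, highest other 5). Both tests were chosen after the result was seen, so chance is less likely there but not excluded. Taking in each split the covariate fit, of 5, that called most, 2 of 100 reached 76, the highest other giving 1709, which points to a structure of the samples that was not traced; picking this fit among settings other than covariates is not covered. The 59 members over the other described lists (2 of 100, highest other 92) decide nothing, since those lists were picked after their results were seen. Over all 49 lists and either direction 4 of 100 splits, the real one among them, reached the 82 members (highest other 133). Chance is less likely there but not excluded, since the test and this adjustment were chosen after the result was seen.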

How the results depend on the processing

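Fits with 3 tissue covariates or a depth covariate, those without 2 low-weight or 2 shallowest libraries, and the recounts over a list alone were chosen only after the result was seen. Of 109 named genes 89 kept their sign under every setting run, and the median of the cell cycle list was positive in 34 of 34 (0.43 to 0.72). Many of these genes were named for a small p in the same libraries. Every setting refitted all or most of those libraries, so a kept sign is no independent support. Estimated depth was low in some libraries, which limits low genes most. The cause of the differences below was not tested, unless stated. Array weights called 740 higher, 329 lower and 95 at least 2-fold, the myelin covariate 60, 16 and 27, and TPM 0, 1 and 1; TPM moved the median of all genes by -0.15. Camera with the preset correlation called 25 lists higher and 4 lower, and fry 1, a count that ran from 0 to 18 over the settings. The 19 cell cycle members became 6 with the stricter filter (fewer members tested) and 11 with 3 covariates.

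Signs turned as follows, in log2. Array weights gave OLFML3 -0.12, VCAN -0.026, NFKBIA -0.015 and UCHL1 0.046. The myelin covariate gave GFAP 0.20, PTGDS 0.26, SOD1 -0.028, MCM5 0.029 and NTRK2 0.052. The fibroblast covariate gave COL1A1 -0.31, COL1A2 -0.10, DCN -0.016, OLFML3 -0.15, VCAN -0.14, NFKBIA -0.13, GFAP 0.0084, UCHL1 0.075, SAG 0.13 and CCNA2 0.055. All 3 covariates gave COL1A1 -0.37, COL1A2 -0.16, DCN -0.096, VCAN -0.011, NFKBIA -0.19, GFAP 0.19, MBP 0.052 and NTRK2 0.11. The photoreceptor covariate gave SPP1 -0.12 and SAG 0.12, and the depth covariate EDNRB -0.028. TPM gave NFKBIA -0.12, SPP1 -0.14, EDNRB -0.077 and SOD1 -0.14, quantile normalization VIM -0.040, NFKBIA -0.0092, SPP1 -0.11 and SOD1 -0.12, and FPKM as deposited NFKBIA -0.020, SPP1 -0.035 and SOD1 -0.042. Without the 2 low-weight libraries OLFML3 was -0.0073, VCAN -0.020, NFKBIA -0.056, SPP1 -0.10, SAG 0.12 and CCNA2 0.019. Without the 2 shallowest SPP1 was -0.013, LTBP2 0.038, SAG 0.085 and EDNRB -0.067. With a median list score the correlations were 0.74, 0.76 and 0.67 (adjusted permutation p = 0.0764, 0.0575 and 0.0764).

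Leaving out 1 library gave 0 to 26 genes higher, 0 to 17 lower and 0 to 21 at least 2-fold (26, 17 and 21 without FCG replicate 1). Ranges were -0.094 to 0.13 for NFKBIA, -0.14 to 0.24 for SPP1, -0.24 to 0.11 for GFAP, -0.31 to 0.18 for PTGDS, -0.093 to 0.016 for GLUL, -0.78 to 0.16 for SAG, -0.081 to 0.32 for EDNRB, -0.057 to 0.096 for SOD1 and 0.00363 to 0.0123 for the excess distance.

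The replicate block over 12 libraries called 0 genes, as the same libraries did without it, and 7 cell cycle members against 10. The fry adjusted p of the cell cycle list was 0.201 with the block and 0.0483 without it, on either side of the threshold. Both fits gave COL1A1 -0.18, VCAN -0.046, NFKBIA -0.14, GFAP 0.035 and UCHL1 0.0029. The labels do not say that numbers pair cats: correlations of same-numbered libraries were over 0.1 in 3 of 6 pairs, and 1 of 6 FCG and 1 of 6 Normal libraries correlated best with their own number.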

Other observations

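The lists below were described only after their results were seen, and the count over the other described lists, which includes them, was tested only after the result was seen. Oxidative stress genes had a median log2 fold change of 0.22, with 0 of 16 past the threshold over all genes and 3 higher when adjusted over the list alone. These were NFE2L2, the regulator of antioxidant genes (0.29), the thioredoxin gene TXN (0.53) and GPX3 (0.56), while PRDX1 stood at 0.30 and SOD1 at 0.02, the latter negative with FPKM as deposited, rescaled to TPM or quantile normalized. Of 15 immediate early genes 0 passed over all genes and 3 when adjusted over the list alone, the cytokine feedback inhibitor gene SOCS3 (1.03), ATF3 (0.79) and MYC (0.68), with EGR1 at 0.67 and IER3 at 0.38. Of 17 endothelin and neurotrophic factor genes 0 passed over all genes and 3 when adjusted over the list alone, LIF (1.07), OSMR (0.79) and the endothelin receptor gene EDNRA (0.74), whereas EDNRB stood at 0.08 and NTRK2 at -0.19. Each of these counts became 0 in at least 1 fit that left out a library, such as that without Normal replicate 1. The camera adjusted p was 0.426, 0.426 and 0.550 with an estimated correlation.

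Type I interferon response genes had a median of -0.29, with 3 of 19 members positive and IFI6 at -0.34. Of the 19, 0 passed over all genes and 0 when adjusted over the list alone (camera adjusted p = 0.624 with an estimated correlation).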
